A study of Homo sapiens with 101 samples.

How the data were processed

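The samples were HT1080 cells given 1 of 11 compounds or left as controls, in 17 groups of 100 replicates on 101 Affymetrix HT HG-U133+ PM arrays. Each array had 54715 probe sets. The deposited values are log2 probe set summaries that the authors made with Partek and GCRMA per the submitters' processing notes, which give no versions. The quantiles of the arrays were alike within 6 sets and differed between them, so the sets look normalized apart. One set holds DMSO_pooled and the 6 compounds set against it, and the other 5 hold BRO, CUR, ETP, MMS or QUE with its control. Nothing was renormalized for the results given as found. The values reached down to background, with a lower 5% from 1.70 in the BRO set to 2.48 in the ETP set, and signal over background and the number of arrays limit the precision.

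Of 54613 probe sets that are not array controls, 40914 were assigned to 1 gene, 864 to several genes and 12835 to none by the array's annotation. Gene names were matched to a GRCh38.p14 gene list, used here only for names and genomic spans, and 56 found no match. For each of 19774 genes the probe set with the highest mean over all arrays was used, which does not look at the groups. A gene was tested where at least 1 of 17 groups had a mean log2 value of 4 or more, which left 11496 genes. The ETP_DMSO replicate 2 array and the array labelled 2-2 were averaged, since the SD of their difference was 0.154 and the next closest pair of that group had 0.242.

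Each compound was compared with its control by a fit of both groups in limma 3.58.1 under R 4.3.3 with data.table (version 1.17.8), with empirical Bayes variances and Benjamini-Hochberg adjustment over the genes of that comparison. A gene was called changed at an adjusted p under 0.05 and a fold change of at least 1.5. Differences between compounds came from 1 fit of all 17 groups. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6. Of 23 gene lists, 21 had at least 3 tested members and were tested against the other genes with camera at a preset correlation of 0.01, adjusted over 231 tests, and again with an estimated correlation. Means of the p53, NRF2 and G2/M lists per sample were compared by exact two-sided permutation, adjusted over the comparisons and these lists, with 95% intervals from the same samples. The permutation did not keep replicate pairs. The lists, comparisons, thresholds, named-gene rule and most alternatives were fixed before the data were examined.

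Genes were named by a rule. A fixed panel of regulators and markers, which includes CDKN1A and MDM2, was named whatever its result, as far as space allowed. Added to it were the 8 called genes with the largest rise and the 8 with the largest fall among those with every treated sample on 1 side of every control, and up to 4 members of a described list with the largest change. Across compounds, 20 genes called the same way in most of them were named. Members of the rule whose call rested on 1 library were left out of the text where space was short. Some genes of the panel were not analysed here.

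Whether the replicate numbers pair a compound with its control was checked from the correlation of replicate deviations over 25537 probe sets. Every pair had r over 0.1 in MMC, NCS, H2O2, ENU, GAD, tBHQ, BRO and CUR, so the block is given beside those results where it changed a call or moved a count by over 1.5 times. In MMS r ranged from -0.29 to 0.34, in ETP from 0.055 to 0.54 and in QUE from 0.091 to 0.54, and these were read as unpaired. Over the tested genes alone the ranges were -0.13 to 0.32, -0.0023 to 0.65 and 0.16 to 0.65, so in QUE the reading depends on the features used. The check kept the libraries labelled ETP replicate 2 and QUE replicate 2, which stood apart from their groups. A low r in ETP or QUE therefore does not show that their numbers are unpaired. No other batch was given by the labels.

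The alternatives were no filter and a filter at 6, the mean of a gene's probe sets, every probe set on its own, an equal median for each array, quantile normalization, 1 fit of all groups, variances with a trend and robust estimation, no fold minimum, the replicate block, the estimated correlation, the treatment of the repeated array, and leaving out each replicate in turn. Alternatives chosen after seeing the data left out the libraries labelled ETP replicate 2, QUE replicate 2, QUE replicates 2 and 3, MMS_CTL replicate 3 or CUR_DMSO replicate 5, or another library that stood apart in QUE, QUE_DMSO, H2O2, MMS or tBHQ, with the list tests repeated, used the block without the number-2 libraries of ETP and QUE, left out list members shared with another list, or set group means under 4 to 4. The method was tested on simulated data. With a 2-fold change it recovered 98.5% of 67 genes in MMC, 92.5% in NCS, 95.5% in H2O2, 91.0% in ENU, 98.5% in GAD, 92.5% in tBHQ, 95.5% in BRO, 95.5% in MMS, 98.5% in CUR, 83.6% in ETP and 86.6% in QUE, with 1 to 6 false calls. A simulated shift of 0.3 in the p53 list was recovered as 0.26 to 0.33, and 0 of 20 unchanged lists were called in each comparison. Each gene was simulated independently, so these counts do not test list calls whose members vary together.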

Results

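Transcript levels were measured in HT1080 cells, a human fibrosarcoma line with intact p53, on 101 arrays in 17 groups, 11 of cells given a compound and 6 of controls. The series text gives 1 dose of each compound, picked for a 1.5-fold rise of total p53 protein, and no exposure time. Mitomycin C (label MMC, 0.1 µM), neocarzinostatin (NCS, 10 ng/ml), hydrogen peroxide (H2O2, 100 µM), ethylnitrosourea (ENU, 2 mM), GAD (2 mM) and tert-butylhydroquinone (tBHQ, 200 µM) were set against the control labelled DMSO_pooled. That tie was inferred, and the labels do not say what was pooled. BRO (600 µM), curcumin (CUR, 10 µM), etoposide (ETP, 0.3 µM) and quercetin (QUE, 30 µM) had labelled DMSO controls of their own, and methyl methanesulfonate (MMS, 200 µM) had the control MMS_CTL. The deviations of the ETP and QUE controls from their group means correlated between samples of the same number (r from 0.33 to 0.86 over tested genes, each highest with its own number), so these controls are not shown to be independent. GAD and BRO are kept as codes because the labels do not spell them out. MMC and H2O2 had 5 replicates and every other group had 6, with 1 ETP_DMSO replicate arrayed again and averaged. Each set of a compound with its control had its own median log2 signal, from 2.88 to 2.92 in the BRO set up to 3.48 to 3.54 in the ETP set. Each compound was therefore compared with its control within its set. The number of arrays limits the precision.

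Every compound changed transcript levels relative to its control, and the number of genes changed ranged from 19 in MMC to 3011 in GAD among 11496 tested. The other counts were 107 in H2O2, 253 in CUR, 281 in NCS, 308 in ETP, 850 in BRO, 1130 in tBHQ, 1249 in ENU, 1267 in MMS and 1499 in QUE. A change means an adjusted p under 0.05 in limma and at least 1.5-fold, values after gene symbols are log2 fold changes ± standard errors, and the p-values measure the spread between these samples, which the labels do not describe as separate cultures. Genes named as the largest rises or falls had every treated sample on 1 side of every control, which chance gives in 0.216% of genes, or 0.433% with 5 treated samples. A gene with a group mean under 4, the level of the filter, was taken as not well above background in that group, and its change is given against 4, as "at least" a rise or "or lower" for a fall, although genes were ranked on the measured difference. This held for 3 of the genes called in MMC and up to 413 in GAD. The level of 4 was the same in every set, although the lower 5% of values ran from 1.70 in the BRO set to 2.48 in the ETP set. These bounds are therefore not alike between sets.

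**Figure D1:**
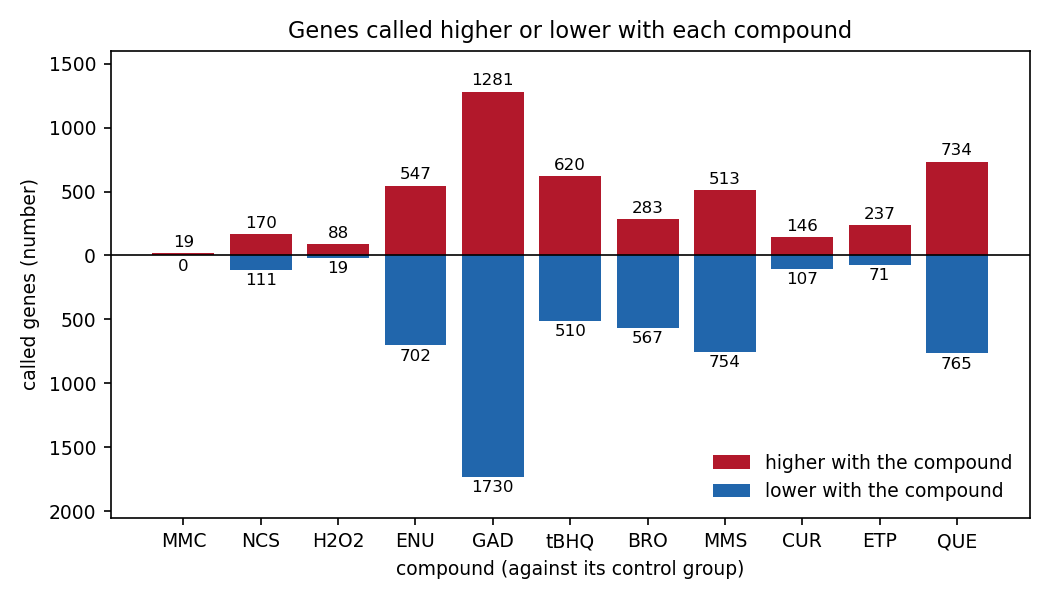
Number of genes called higher (upward bars) and lower (downward bars) for each compound against its control, of 11496 tested. The largest counts were 1281 higher and 1730 lower in GAD, and MMC had 19 higher and 0 lower.

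The p53 target list, genes that p53 is known to switch on, rose against the control in 10 of 11 compounds, and tBHQ was the other. With an estimated correlation 5 of these calls were lost, with an adjusted p = 0.45 in GAD, 0.16 in BRO, 0.34 in MMS, 0.74 in CUR and 0.15 in QUE. Among 47 tested members the median log2 fold change was 0.89 in ETP, 0.74 in ENU, 0.66 in NCS, 0.62 in QUE, 0.60 in H2O2, 0.50 in MMS, 0.48 in GAD, 0.43 in MMC, 0.30 in BRO, 0.13 in CUR and -0.15 in tBHQ. In 9 compounds every treated sample had a higher mean over the list than every control, with an exact two-sided permutation p = 0.0022 (adjusted p = 0.0042), the smallest these sample numbers allow. CUR had a difference of 0.16 (95% interval 0.03 to 0.30, exact permutation p = 0.013, adjusted p = 0.020), with 4 of 6 treated samples above every control. In tBHQ the difference was -0.07 (-0.17 to 0.02, exact permutation p = 0.13). CDKN1A, the p21 cell cycle inhibitor, rose in 9 compounds. Its mean over all probe sets stayed under 1.5-fold in MMC (0.47), NCS (0.52), H2O2 (0.58), ENU (0.46), MMS (0.54) and QUE (0.36).

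**Figure D2:**
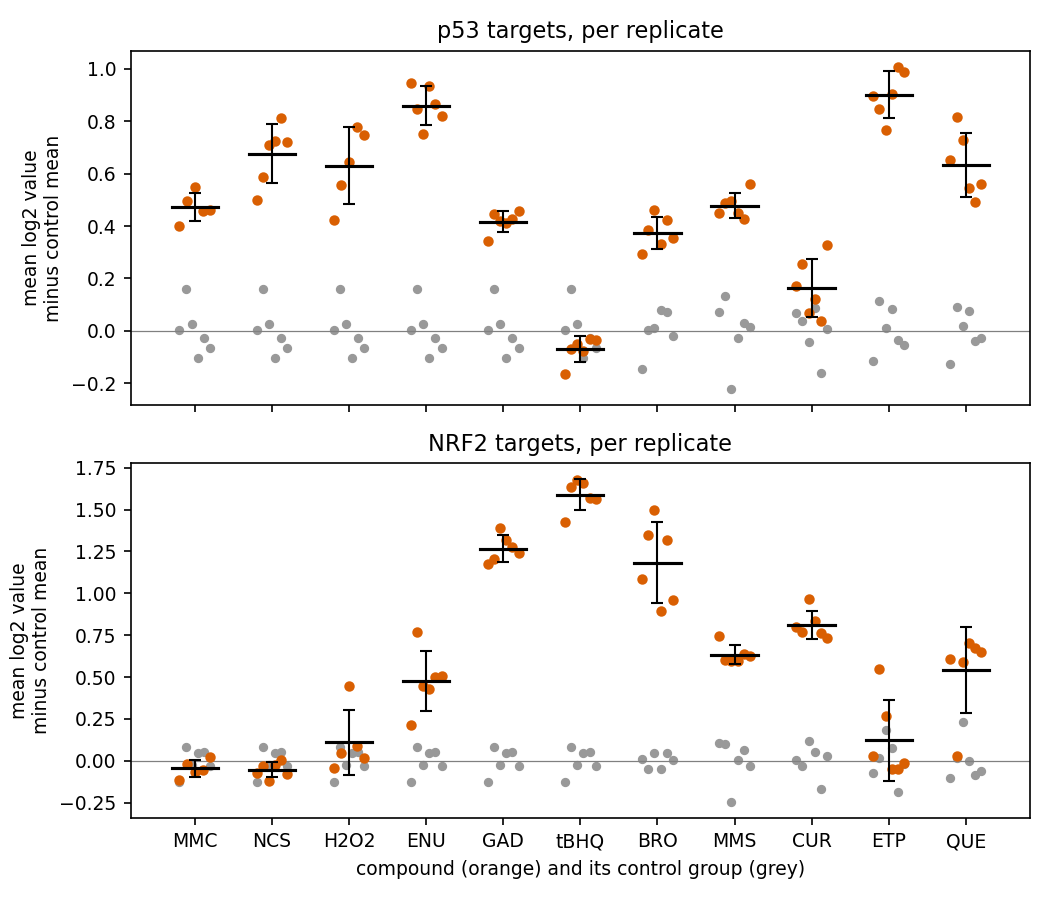
Mean log2 value of the p53 and NRF2 target lists in each replicate, minus the mean of its control replicates. Orange points are compound replicates, grey points control replicates, black bars means and error bars SD, with the p53 list lowest in tBHQ at -0.07 and highest in ETP at 0.90.

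MMC, a DNA crosslinking drug, had the fewest calls, 19 genes that were all higher, 9 of them p53 targets (n = 5 treated and 6 control samples). Of the p53 targets, 9 of 47 rose (16 adjusted over the list alone, median 0.43, adjusted p = 3.1e-52, adjusted p = 0.0028 with an estimated correlation). Examples were DDB2, a damage recognition factor of nucleotide excision repair, at 0.76 ± 0.08, and CDKN1A at 0.70 ± 0.08. MDM2, the ligase that degrades p53, had 0.67 ± 0.13 (adjusted p = 0.067). The largest other rises included CCDC148 (at least 0.41), STOM (0.95 ± 0.12) and SUGCT (0.94 ± 0.11). TP53INP1 rose by 0.94 ± 0.13 but had 0.31 as a mean of probe sets. Genes of G1/S and replication were lower as a list, where 0 of 31 fell (2 adjusted over the list alone, median -0.23, adjusted p = 1.8e-08, adjusted p = 0.56 with an estimated correlation). MCM6, a subunit of the replicative helicase, had -0.78 ± 0.15. Of the ATF4 and stress response genes, 0 of 24 fell and 0 rose (2 and 1 adjusted over the list alone, median -0.13, adjusted p = 0.00030, adjusted p = 0.59 with an estimated correlation), and SLC7A11, the cystine carrier, had -0.87 ± 0.27. The interferon-stimulated list was higher, where 0 of 16 rose (0 adjusted over the list alone, median 0.19, adjusted p = 3.7e-05, adjusted p = 0.16 with an estimated correlation). IFIT1 had 0.59 ± 0.19. With group means under 4 set to 4 that median was 0.10. No gene was called lower by limma, against 245 lower at an unadjusted p under 0.05, a number that chance alone can give among 11496 genes. Without MMC replicate 4, and likewise without DMSO_pooled replicate 4, 11 genes were called, and with the replicate number as a block 60 were called, 49 higher and 11 lower, among them MDM2 (0.60, adjusted p = 0.0044), MCM6 (-0.82, adjusted p = 0.0033) and SLC7A11 (-0.80, adjusted p = 0.0033). The block called 14 p53 targets higher, and 3 G1/S and 2 ATF4 genes lower. It also gave calls to the G2/M list (median -0.05, adjusted p = 0.0025, adjusted p = 0.54 with an estimated correlation), the cholesterol list (-0.08, 0.0048 and 0.54) and, upward, the matrix list (0.11, 0.00093 and 0.45), which had an adjusted p of 0.61, 0.099 and 0.057 without it.

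NCS, a radiomimetic that breaks DNA, changed 281 genes, 170 higher and 111 lower (n = 6 and 6). Among p53 targets, 24 of 47 rose (25 adjusted over the list alone, median 0.66, adjusted p = 1.1e-34, adjusted p = 0.029 with an estimated correlation). ACER2, a ceramidase, rose by at least 1.09, SPATA18, a mitochondrial quality factor, by at least 1.02, TP53I3 by 1.13 ± 0.20, CDKN1A by 1.05 ± 0.11, FAS, a death receptor, by 0.96 ± 0.20, MDM2 by 0.92 ± 0.11 and SESN1 by 0.87 ± 0.12. Of the histone genes, 6 of 11 rose (7 adjusted over the list alone, median 0.63, adjusted p = 6.5e-07, adjusted p = 0.32 with an estimated correlation). H2BC4 had 1.51 ± 0.18 and H2BC21 1.33 ± 0.18. Of the G1/S and replication genes, 13 of 31 fell (22 adjusted over the list alone, median -0.79, adjusted p = 2.7e-14, adjusted p = 0.47 with an estimated correlation), and the examples were CDC45 at -1.44 ± 0.31, MCM6 at -1.37 ± 0.28, MCM2 at -1.24 ± 0.26 and MCM5 at -1.14 ± 0.19. Of the G2/M genes, 4 of 35 fell (7 adjusted over the list alone, median -0.50, adjusted p = 8.4e-16, adjusted p = 0.47 with an estimated correlation). The proliferation marker MKI67 had -0.91 ± 0.20 and CKAP2L -0.70 ± 0.11. Of the homologous recombination and Fanconi genes, 4 of 24 fell (9 adjusted over the list alone, median -0.47, adjusted p = 7.1e-10, adjusted p = 0.43 with an estimated correlation). BARD1, the partner of BRCA1, had -1.02 ± 0.19. In base excision repair 2 of 18 fell (3 adjusted over the list alone, median -0.21, adjusted p = 0.0057, adjusted p = 0.16 with an estimated correlation). UNG, the uracil glycosylase, had -0.92 ± 0.20. It is also in the G1/S list, and without it 1 of 17 fell (adjusted p = 0.018). Of the ATF4 genes, 8 of 24 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.23, adjusted p = 0.00034, adjusted p = 0.56 with an estimated correlation), and asparagine synthetase ASNS at -1.47 ± 0.31, SLC7A11 at -1.40 ± 0.21 and SLC7A5 at -1.02 ± 0.18 were among the largest falls of all. Outside the lists the largest rises included SULF2 (at least 0.85), NECTIN4 (1.60 ± 0.18), CDH10 (at least 1.56) and CCDC148 (at least 0.71), and the falls included KIF15, a mitotic kinesin (-1.21 ± 0.27), RMI2 (-1.01 ± 0.14) and PAQR4 (-0.97 ± 0.17). Without NCS replicate 1, 502 genes were called, 223 higher and 279 lower, and with the replicate block 428 were, 221 higher and 207 lower. The block called 22 G1/S, 7 G2/M and 9 recombination genes lower and ended the call of nucleotide excision repair (adjusted p = 0.11 against 0.040, or 0.29 with an estimated correlation and no block), which was also lost without DDB2 and XPC, members of the p53 list as well (0.26).

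H2O2, an oxidant, changed 107 genes, 88 higher and 19 lower (n = 5 and 6). Of the p53 targets, 21 of 47 rose (25 adjusted over the list alone, median 0.60, adjusted p = 6.5e-37, adjusted p = 0.032 with an estimated correlation). ACER2 had at least 0.87, TP53INP1 1.34 ± 0.18, SPATA18 at least 0.88, CDKN1A 1.01 ± 0.11 and MDM2 0.88 ± 0.11. Of the G1/S genes, 3 of 31 fell (10 adjusted over the list alone, median -0.54, adjusted p = 7.1e-12, adjusted p = 0.49 with an estimated correlation). MCM5 had -0.89 ± 0.13. The G2/M list was called with a negative median, where 0 of 35 fell (0 adjusted over the list alone, median -0.49, adjusted p = 1.2e-11, adjusted p = 0.55 with an estimated correlation). Its mean per sample did not pass, at -0.47 (95% interval -1.10 to 0.19, exact permutation p = 0.097, adjusted p = 0.14), with 3 of 5 treated samples below every control. MKI67 had -0.86 ± 0.28 and CDC20 -0.67 ± 0.29. With the replicate block 7 of the list fell, among them MKI67 (-0.84, adjusted p = 0.041) and CDC20 (-0.63, adjusted p = 0.024). The histone list was higher, where 0 of 11 rose (2 adjusted over the list alone, median 0.32, adjusted p = 0.0031, adjusted p = 0.55 with an estimated correlation). H2BC4 had 0.76 ± 0.21. In nucleotide excision repair 2 of 19 rose (2 adjusted over the list alone, median 0.09, adjusted p = 0.022, adjusted p = 0.39 with an estimated correlation). DDB2 had 0.83 ± 0.14. Without DDB2 and XPC, which are also in the p53 list, the call was lost (median 0.08, adjusted p = 0.17), and 1 member rose without H2O2 replicate 3. The NF-kB and inflammatory list was higher, where 0 of 18 rose (0 adjusted over the list alone, median 0.30, adjusted p = 0.0045, adjusted p = 0.30 with an estimated correlation). IL6 had 0.65 ± 0.31. The NRF2 list was not called (adjusted p = 0.72). Its member AKR1B10, an aldo-keto reductase, had 1.72 ± 0.42 (adjusted p = 0.062) and HMOX1, heme oxygenase, 0.44 ± 0.34. With the block the list was not called either (adjusted p = 0.38), while 2 members rose, AKR1B10 (1.65, adjusted p = 0.039) and AKR1C1 (0.93, adjusted p = 0.028). Outside the lists CCDC148 (at least 1.25), CCDST (2.07 ± 0.26), NECTIN4 (1.65 ± 0.23), SPANXC (1.55 ± 0.18) and SUGCT (1.36 ± 0.14) rose, and SCARA3 fell (-1.12 ± 0.16). The count depended on single libraries, with 167 without H2O2 replicate 1, 69 without replicate 3, 35 without replicate 5 and 71 without replicate 6, and 41, 61 and 60 without DMSO_pooled replicates 4, 5 and 6. H2O2 replicate 3 stood apart in the NRF2 list, at 8.60, and without it the G2/M median was -0.28 (adjusted p = 2.3e-07) and 1 G1/S gene fell. With the replicate block 224 genes were called, 147 higher and 77 lower, among them GDF15 (0.70, adjusted p = 0.0054) and H2BC4 (0.68, adjusted p = 0.0061), and 68 were called with the mean of probe sets and 167 in 1 fit of all groups. The block called 13 G1/S genes lower, and 2 histone and 2 inflammatory genes higher. It also gave calls to the cholesterol list (median -0.10, adjusted p = 0.012, adjusted p = 0.30 with an estimated correlation) and, upward, the matrix list (0.11, 0.015 and 0.62), which had an adjusted p of 0.064 and 0.13 without it, and ended that of the ATF4 list (adjusted p = 0.22 against 0.034, or 0.76 with an estimated correlation and no block), which was also lost without H2O2 replicate 2 (0.19).

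ETP, a topoisomerase II poison, gave the highest p53 list median of the series (n = 6 and 6). It changed 308 genes, 237 higher and 71 lower. Among p53 targets, 33 of 47 rose (34 adjusted over the list alone, median 0.89, adjusted p = 2.0e-45, adjusted p = 0.0028 with an estimated correlation). Their largest rises were ACER2 at 2.08 ± 0.16, TP53INP1 at 2.05 ± 0.12, TP53I3 at 1.97 ± 0.20 and SPATA18 at 1.63 ± 0.21, and FAS (1.62 ± 0.12), CDKN1A (1.32 ± 0.09), MDM2 (1.18 ± 0.09), SESN1 (1.16 ± 0.14) and GDF15, a secreted stress cytokine (0.97 ± 0.18), rose too. Among G1/S genes, 10 of 31 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.43, adjusted p = 3.3e-08, adjusted p = 0.55 with an estimated correlation). MCM6 had -1.81 ± 0.29, POLA1, a subunit of DNA polymerase alpha, -1.15 ± 0.15, and CDCA7, outside the list, -1.19 ± 0.22. In nucleotide excision repair 2 of 19 rose (2 adjusted over the list alone, median 0.09, adjusted p = 0.023, adjusted p = 0.30 with an estimated correlation). DDB2 had 1.22 ± 0.12 and XPC, a lesion sensor, 1.20 ± 0.11. Both are also in the p53 list, and without them the call was lost, with 0 of 17 higher (median 0.07, adjusted p = 0.29), so it may restate the p53 rise. Among G2/M genes, 1 of 35 fell (0 adjusted over the list alone, median -0.45, adjusted p = 8.1e-06, adjusted p = 0.71 with an estimated correlation). The list mean per sample did not pass, at -0.47 (95% interval -1.28 to 0.14, exact permutation p = 0.19, adjusted p = 0.24). CCNB1, the mitotic cyclin, had -0.63 ± 0.47, or -0.11 ± 0.13 (adjusted p = 0.64) without the library labelled ETP replicate 2. The ATF4 list was lower, where 0 of 24 fell and 1 rose (3 and 1 adjusted over the list alone, median -0.33, adjusted p = 0.028, adjusted p = 0.75 with an estimated correlation), although its member ATF3 rose by 1.57 ± 0.28. The interferon list was higher, where 0 of 16 rose (0 adjusted over the list alone, median 0.23, adjusted p = 0.0074, adjusted p = 0.36 with an estimated correlation). IFIT3 had 0.50 ± 0.12. Outside the lists TREM2, a myeloid surface receptor, rose by at least 3.20, NECTIN4 by 2.64 ± 0.25, CCDC148 by at least 1.41, MEGF6 by at least 1.83 and SULF2 by at least 1.55, and AKR1B10 by 2.44 ± 0.24. The library labelled ETP replicate 2 stood apart in the G2/M list, with a mean of 7.35. Without it 455 genes were called, 306 higher and 149 lower, 275 of them shared with the full set. The G2/M median was then -0.15 (adjusted p = 0.041), the ATF4 median -0.43 with 10 members lower (adjusted p = 2.2e-05), the nucleotide excision repair median 0.04 (adjusted p = 0.037), and 3 histone genes rose (adjusted p = 0.0064). The calls of the cholesterol list (-0.23, adjusted p = 0.042, adjusted p = 0.74 with an estimated correlation) and the chaperone list of the unfolded protein response (0.15, 0.028 and 0.63) were lost (adjusted p = 0.15 for each).

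ENU, an ethylating agent, changed 1249 genes, 547 higher and 702 lower (n = 6 and 6). Of the p53 targets, 30 of 47 rose (30 adjusted over the list alone, median 0.74, adjusted p = 8.8e-22, adjusted p = 0.027 with an estimated correlation). ACER2 had at least 2.18, TP53I3 2.48 ± 0.22, the phosphatase PPM1D 2.10 ± 0.17, FAS 2.09 ± 0.20, SESN1 1.66 ± 0.13, GDF15 0.98 ± 0.17, CDKN1A 0.81 ± 0.08 and MDM2 0.66 ± 0.10. Of the apoptosis genes, 5 of 18 rose (5 adjusted over the list alone, median 0.13, adjusted p = 0.026, adjusted p = 0.36 with an estimated correlation). APAF1, the apoptosome scaffold, had 1.53 ± 0.13, BBC3 0.80 ± 0.16 and PMAIP1 0.77 ± 0.09. Without BAX and BBC3, which are also in the p53 list, 4 of 16 rose and the call was lost (median 0.12, adjusted p = 0.090). Of the NRF2 targets, 5 of 26 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.00044, adjusted p = 0.45 with an estimated correlation). AKR1B10 had 4.44 ± 0.42, NQO1 0.92 ± 0.11 and HMOX1 0.78 ± 0.15. Of the heat shock genes, 4 of 19 rose (4 adjusted over the list alone, median 0.18, adjusted p = 0.014, adjusted p = 0.74 with an estimated correlation). The small chaperone CRYAB had at least 3.91 and HSPA4L 1.55 ± 0.20. Of the G1/S genes, 8 of 31 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.29, adjusted p = 0.0027, adjusted p = 0.76 with an estimated correlation). POLA1 had -1.34 ± 0.14 and MCM6 -1.09 ± 0.13. Among histone genes, 5 of 11 fell (5 adjusted over the list alone, median -0.53, adjusted p = 0.00065, adjusted p = 0.47 with an estimated correlation). H2BC5 had -0.74 ± 0.12. Of the hypoxia and glycolysis genes, 4 of 15 fell (4 adjusted over the list alone, median -0.35, adjusted p = 0.00047, adjusted p = 0.47 with an estimated correlation). The kinase PDK1 had -1.52 ± 0.08 and ALDOC -0.98 ± 0.25. Of the G2/M genes, 2 of 35 rose (2 adjusted over the list alone, median 0.16, adjusted p = 0.036, adjusted p = 0.84 with an estimated correlation). The list mean per sample did not pass, at 0.18 (95% interval -0.13 to 0.49, exact permutation p = 0.19, adjusted p = 0.24), with 2 of 6 treated samples above every control. CDK1 had 0.78 ± 0.11. The stress factor ATF3 rose by 2.44 ± 0.20. Outside the lists TREM2 (at least 3.61), CEACAM1 (at least 2.33), HECW2 (3.10 ± 0.18) and CYP4F2 (at least 1.38) rose, and LRRC17 (-2.78 ± 0.25), PDE7B (-2.60 ± 0.36), SNAP25 (-2.50 ± 0.31), MAP2K6 (-1.33 or lower) and PAPPA (-1.99 ± 0.32) fell.

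MMS, a methylating agent, changed 1267 genes (n = 6 and 6), 513 higher and 754 lower, or 30.2% higher after a shift of medians against 40.5% as deposited. Among p53 targets, 18 of 47 rose and 1 fell (18 and 1 adjusted over the list alone, median 0.50, adjusted p = 6.9e-09, adjusted p = 0.34 with an estimated correlation). ACER2 had at least 1.32, TP53I3 1.32 ± 0.09, PPM1D 1.30 ± 0.09, CDKN1A 1.10 ± 0.11, FAS 0.98 ± 0.15 and MDM2 0.92 ± 0.08. Among homologous recombination and Fanconi genes, 13 of 24 rose (13 adjusted over the list alone, median 0.74, adjusted p = 9.5e-08, adjusted p = 0.47 with an estimated correlation). FANCB had 1.17 ± 0.12, the nuclease EXO1 1.09 ± 0.14, RAD51C 1.05 ± 0.15 and FANCI 1.04 ± 0.16. Among G1/S genes, 12 of 31 rose (12 adjusted over the list alone, median 0.35, adjusted p = 0.019, adjusted p = 0.82 with an estimated correlation). MCM10 had 1.27 ± 0.28, the kinase CDC7 1.05 ± 0.18 and the licensing factor CDT1 0.94 ± 0.09. Of the histone genes, 8 of 11 fell (8 adjusted over the list alone, median -0.73, adjusted p = 6.0e-06, adjusted p = 0.35 with an estimated correlation). H2AC6 had -1.52 ± 0.13 and H2BC4 -1.38 ± 0.24. Among NRF2 targets, 9 of 26 rose (9 adjusted over the list alone, median 0.50, adjusted p = 4.6e-08, adjusted p = 0.19 with an estimated correlation). AKR1C1 had 4.19 ± 0.27, SLC7A11 1.71 ± 0.09 and NQO1 1.32 ± 0.08. HMOX1 went the other way, both with all libraries and without MMS_CTL replicate 3. In that second fit HMOX1 had -0.53 ± 0.13 (adjusted p = 0.0056) and SRXN1 0.51 ± 0.07, both under 1.5-fold. Among heat shock genes, 4 of 19 rose (4 adjusted over the list alone, median 0.35, adjusted p = 4.7e-06, adjusted p = 0.45 with an estimated correlation). HSPA1A had 1.03 ± 0.08. Of the unfolded protein response chaperones, 3 of 20 fell (3 adjusted over the list alone, median -0.26, adjusted p = 1.1e-05, adjusted p = 0.30 with an estimated correlation). HERPUD1 had -0.94 ± 0.08. Of the matrix and TGF-beta genes, 13 of 22 fell (13 adjusted over the list alone, median -0.76, adjusted p = 5.6e-08, adjusted p = 0.30 with an estimated correlation). The collagen genes COL1A1 and COL5A1 had -2.27 ± 0.43 and -2.01 ± 0.23, and the protease inhibitor TIMP3 -1.45 or lower. Base excision repair was not called as a list (median 0.22, adjusted p = 0.084, or 0.037 after a shift of medians), although PARP2 rose by 0.89 ± 0.14 and NEIL3 by 0.84 ± 0.20. Other large changes were rises of CSTA (at least 1.88) and KYNU (at least 2.03) and falls of LRRC17 (-3.37 ± 0.22), SNAP25 (-2.85 ± 0.15), TENM4 (-2.37 or lower) and VCAN, a matrix proteoglycan (-2.43 ± 0.16). MMS_CTL replicate 3 stood apart in CDKN1A (8.10) and upper quartile (5.54), and without it 1219 genes were called, 359 higher and 860 lower, 1088 of them shared. The G1/S median was then 0.21 with 9 members higher (adjusted p = 0.031).

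GAD changed the most genes of the series, 3011, with 1281 higher and 1730 lower (n = 6 and 6). Of the NRF2 targets, 17 of 26 rose (17 adjusted over the list alone, median 0.92, adjusted p = 7.1e-10, adjusted p = 0.076 with an estimated correlation). AKR1C1 had 6.02 ± 0.12, HMOX1 2.63 ± 0.16, SRXN1 1.72 ± 0.06 and NQO1 1.38 ± 0.07. Among ATF4 genes, 17 of 24 rose and 2 fell (17 and 2 adjusted over the list alone, median 1.00, adjusted p = 6.0e-05, adjusted p = 0.54 with an estimated correlation). SLC7A11 had 3.27 ± 0.18, NUPR1 at least 2.08, ATF3 2.38 ± 0.20 and DDIT3, the factor CHOP, 0.99 ± 0.24. Of the p53 targets, 20 of 47 rose and 4 fell (20 and 4 adjusted over the list alone, median 0.48, adjusted p = 0.0025, adjusted p = 0.45 with an estimated correlation). SERTAD1 had 1.81 ± 0.13, CDKN1A 1.36 ± 0.07, GDF15 1.18 ± 0.15 and MDM2 0.96 ± 0.11, against TNFAIP8 at -1.62 ± 0.12. Of the heat shock genes, 6 of 19 rose (6 adjusted over the list alone, median 0.46, adjusted p = 0.0028, adjusted p = 0.71 with an estimated correlation). HSPB8 had 1.64 ± 0.22 and HSPA1A 1.22 ± 0.20. In the metallothionein list 2 of 6 rose (2 adjusted over the list alone, median 0.50, adjusted p = 0.033, adjusted p = 0.62 with an estimated correlation). MT1F had 0.74 ± 0.14 and MT1X 0.74 ± 0.09. Among G2/M genes, 24 of 35 fell (24 adjusted over the list alone, median -0.74, adjusted p = 4.5e-07, adjusted p = 0.65 with an estimated correlation). KIF20A had -1.85 ± 0.24, CENPA -1.72 ± 0.25, TOP2A -1.12 ± 0.16 and MKI67 -0.90 ± 0.13. Of the matrix genes, 14 of 22 fell and 2 rose (14 and 2 adjusted over the list alone, median -0.75, adjusted p = 0.00068, adjusted p = 0.47 with an estimated correlation). COL1A1 had -3.02 ± 0.37, THBS1 -2.45 ± 0.22 and TIMP3 -2.19 or lower. Of the interferon genes, 9 of 16 fell (9 adjusted over the list alone, median -0.75, adjusted p = 0.00074, adjusted p = 0.16 with an estimated correlation). OAS1 had -2.17 ± 0.20 and IFIH1, an RNA sensor, -2.07 ± 0.19. With group means under 4 set to 4, which concerned 6 members, that median was -0.17. Of the cholesterol genes, 9 of 17 fell (9 adjusted over the list alone, median -0.61, adjusted p = 0.00071, adjusted p = 0.61 with an estimated correlation). ACAT2 had -1.39 ± 0.15. Among hypoxia genes, 8 of 15 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.59, adjusted p = 0.00071, adjusted p = 0.47 with an estimated correlation). ALDOC had -2.02 ± 0.30. Other large changes were rises of MYCT1 (at least 3.75) and IL13RA2, a decoy receptor (at least 2.34), and falls of GNG2 (-4.13 ± 0.38), SORBS2 (-3.85 ± 0.30), DPYD (-3.82 ± 0.30), PLXNA4 (-3.69 ± 0.28) and TGFB2 (-3.59 ± 0.30). The 3' minus 5' signal of ACTB, a measure of RNA ends, was 0.43 higher in GAD than in its control (95% interval 0.25 to 0.62, exact permutation p = 0.0022, adjusted p = 0.048). That of GAPDH differed by 0.040 (95% interval -0.009 to 0.088, exact permutation p = 0.087, adjusted p = 0.43).

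tBHQ, a phenolic activator of NRF2, gave the highest NRF2 list median of the series without a rise of the p53 list (n = 6 and 6). It changed 1130 genes, 620 higher and 510 lower. Among NRF2 targets, 22 of 26 rose (22 adjusted over the list alone, median 1.31, adjusted p = 1.2e-22, adjusted p = 0.0040 with an estimated correlation). AKR1C1 had 6.22 ± 0.18, HMOX1 4.49 ± 0.11, AKR1B10 2.69 ± 0.41, SRXN1 1.63 ± 0.06 and NQO1 1.31 ± 0.08. Among p53 targets 3 of 47 rose and 1 fell (3 and 1 adjusted over the list alone, median -0.15, adjusted p = 0.071), or adjusted p = 0.034 without DMSO_pooled replicate 4 (-0.20). Without tBHQ replicate 1, which stood apart in this list at 8.07, 3 fell (median -0.13, adjusted p = 0.16). CDKN1A had 0.33 ± 0.08, under the fold minimum, MDM2 -0.12 ± 0.10 and TP53I3 -0.32 ± 0.21, while GDF15 rose by 0.94 ± 0.19 and PLK2 fell, at -1.02 ± 0.08. Of the ATF4 genes, 9 of 24 rose (9 adjusted over the list alone, median 0.40, adjusted p = 0.00013, adjusted p = 0.56 with an estimated correlation). SLC7A11 had 2.90 ± 0.18, the enzyme CTH 1.78 ± 0.30 and DDIT3 1.09 ± 0.29. Of the inflammatory genes, 7 of 18 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.41, adjusted p = 0.045, adjusted p = 0.47 with an estimated correlation). The chemokine CXCL3 had 2.46 ± 0.20, IL1A 1.92 ± 0.41 and IL6 1.79 ± 0.25. That call was lost without tBHQ replicate 4 (adjusted p = 0.059), which stood apart in the ACTB end signal at 0.75. Of the G1/S genes, 14 of 31 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.67, adjusted p = 1.6e-08, adjusted p = 0.56 with an estimated correlation). POLA1 had -1.12 ± 0.16 and UNG -1.06 ± 0.15. Of the G2/M genes, 11 of 35 fell (11 adjusted over the list alone, median -0.43, adjusted p = 3.3e-08, adjusted p = 0.58 with an estimated correlation). NUSAP1 had -1.05 ± 0.13 and CDK1 -0.99 ± 0.11. Among interferon genes, 6 of 16 fell (6 adjusted over the list alone, median -0.34, adjusted p = 0.00034, adjusted p = 0.16 with an estimated correlation). OAS1 had -1.56 ± 0.12. With group means under 4 set to 4 that median was -0.06, and that of the inflammatory list 0.26. Among matrix genes, 7 of 22 fell (8 adjusted over the list alone, median -0.44, adjusted p = 0.0013, adjusted p = 0.55 with an estimated correlation). THBS1 had -2.02 ± 0.17 and TGFBI -1.25 ± 0.14. Other large changes were rises of NRCAM (3.65 ± 0.16), GCNT3 (at least 2.32) and SPP1, osteopontin (2.81 ± 0.23), and falls of FLG, filaggrin (-2.75 or lower), TXNIP, the thioredoxin inhibitor (-3.05 ± 0.45), and KRT80 (-2.40 ± 0.23).

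BRO changed 850 genes (n = 6 and 6), 283 higher and 567 lower, or 45.6% higher after quantile normalization against 33.3% as deposited, and 551 genes were called with the mean of probe sets. Of the NRF2 targets, 17 of 26 rose (17 adjusted over the list alone, median 0.95, adjusted p = 5.8e-22, adjusted p = 0.13 with an estimated correlation). HMOX1 had 4.17 ± 0.22, AKR1C1 3.16 ± 0.31, SLC7A11 2.22 ± 0.13, the glutathione enzyme GCLC 1.85 ± 0.21, NQO1 1.45 ± 0.11 and SRXN1 1.25 ± 0.13. Among p53 targets, 13 of 47 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.30, adjusted p = 3.3e-10, adjusted p = 0.16 with an estimated correlation). CDKN1A had 1.21 ± 0.12, FAS 1.13 ± 0.12, MDM2 1.10 ± 0.12, GDF15 0.91 ± 0.13 and SESN1 0.76 ± 0.09. Among heat shock genes, 4 of 19 rose (4 adjusted over the list alone, median 0.26, adjusted p = 6.5e-07, adjusted p = 0.30 with an estimated correlation). HSPB8 had 1.41 ± 0.33 and DNAJB4 1.33 ± 0.14. Among G1/S genes, 9 of 31 fell (9 adjusted over the list alone, median -0.30, adjusted p = 0.011, adjusted p = 0.81 with an estimated correlation). MCM2 had -0.89 ± 0.19, CDC45 -0.86 ± 0.23 and POLA1 -0.85 ± 0.17. The G2/M list was not called (median -0.18, adjusted p = 0.099), nor was homologous recombination (median -0.25, adjusted p = 0.052). With the replicate block both were (adjusted p = 0.0063 for each, and 0.73 and 0.44 with an estimated correlation). Of the matrix genes, 3 of 22 fell (3 adjusted over the list alone, median -0.29, adjusted p = 0.046, adjusted p = 0.72 with an estimated correlation). TGFBI had -0.75 ± 0.15 and FN1, fibronectin, -0.74 ± 0.14. Other large changes were rises of NMRAL2P, a pseudogene transcript (at least 3.46), and ZSCAN31 (2.18 ± 0.23), and falls of LRRC17 (-2.01 ± 0.24), GALNT15 (-1.87 ± 0.18), NREP (-1.85 ± 0.15), MAP2K6 (-1.31 or lower) and CEMIP, a hyaluronan-binding protein (-1.66 ± 0.20).

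CUR changed 253 genes (n = 6 and 6), 146 higher and 107 lower, or 57.7% higher, against 42.5% after a shift of medians and 44.2% after quantile normalization. Among NRF2 targets, 13 of 26 rose (13 adjusted over the list alone, median 0.59, adjusted p = 3.9e-19, adjusted p = 0.0048 with an estimated correlation). AKR1C1 had 3.20 ± 0.30, AKR1B10 at least 2.02, HMOX1 1.91 ± 0.35, SLC7A11 1.87 ± 0.25, PIR 1.58 ± 0.13 and NQO1 1.05 ± 0.08. Among unfolded protein response chaperones, 0 of 20 fell (0 adjusted over the list alone, median -0.21, adjusted p = 4.5e-07, adjusted p = 0.032 with an estimated correlation). PDIA4 had -0.54 ± 0.11 and MANF -0.52 ± 0.08. Of the p53 targets, 1 of 47 rose (2 adjusted over the list alone, median 0.13, adjusted p = 0.039, adjusted p = 0.74 with an estimated correlation). CDKN1A had 0.51 ± 0.10 and MDM2 0.44 ± 0.13 (adjusted p = 0.071). That list call was lost without CUR replicate 1 (0.12, adjusted p = 0.063), replicate 2 (0.12, 0.11) or replicate 6 (0.10, 0.10), without CUR_DMSO replicate 3 (0.12, 0.17) or replicate 6 (0.15, 0.10), and with the mean of probe sets (0.12, 0.099). Among histone genes, 2 of 11 fell (3 adjusted over the list alone, median -0.25, adjusted p = 0.0013, adjusted p = 0.55 with an estimated correlation). H2AC6 had -1.31 ± 0.16. The G2/M list was called with a negative median, where 0 of 35 fell (0 adjusted over the list alone, median -0.22, adjusted p = 1.2e-07, adjusted p = 0.56 with an estimated correlation). Its mean per sample did not pass, at -0.22 (95% interval -0.51 to 0.06, exact permutation p = 0.097, adjusted p = 0.14), with 1 of 6 treated samples below every control. UBE2C had -0.49 ± 0.10. Among ATF4 genes, 5 of 24 rose and 0 fell (6 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.0055, adjusted p = 0.64 with an estimated correlation). PPP1R15A, a phosphatase subunit that reverses translation arrest, had 0.83 ± 0.14. Among cholesterol genes, 1 of 17 fell (1 adjusted over the list alone, median -0.20, adjusted p = 2.2e-05, adjusted p = 0.47 with an estimated correlation). Among hypoxia genes, 1 of 15 fell (1 adjusted over the list alone, median -0.22, adjusted p = 0.00019, adjusted p = 0.49 with an estimated correlation). Other large falls were LRRC17 (-2.06 ± 0.20), SCG2 (-1.80 ± 0.29), VCAN (-1.51 ± 0.28), MAP2K6 (-1.46 ± 0.18) and SHROOM2 (-1.16 ± 0.17). The count was 155 without CUR replicate 3, 587 without CUR replicate 5, 168 without CUR_DMSO replicate 4 and 448 with the replicate block, 247 higher and 201 lower, with 2 p53 targets higher and 2 hypoxia and 2 ATF4 genes lower. It was 161 with the mean of probe sets and 384 in 1 fit of all groups. Without CUR_DMSO replicate 5, 241 genes were called, 122 higher and 119 lower, 198 of them shared. The G1/S list (-0.14, adjusted p = 0.0099) and the inflammatory list (0.24, adjusted p = 0.017) were then called, and 4 histone genes fell. No cholesterol or hypoxia gene was then called lower, although both lists kept their calls, and 2 p53 targets rose.

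QUE, a plant flavonol, changed 1499 genes, 734 higher and 765 lower (n = 6 and 6). QUE replicate 3 stood apart in the G2/M list, with a mean of 6.86 against 8.18 to 8.81 in the others, and 1186 genes were called without it, 1144 of them shared. Among G2/M genes, 27 of 35 fell (31 adjusted over the list alone, median -1.06, adjusted p = 1.9e-11, adjusted p = 0.54 with an estimated correlation). DLGAP5 had -2.67 ± 0.56, the checkpoint kinase BUB1 -2.18 ± 0.38, KIF20A -2.11 ± 0.38, HMMR -1.90 ± 0.45, CCNB1 -1.54 ± 0.30 and CDC20 -1.54 ± 0.30. Without replicate 3 the median was -0.80 with 26 members lower (adjusted p = 2.0e-16, adjusted p = 0.36 with an estimated correlation). Among p53 targets, 24 of 47 rose and 1 fell (24 and 1 adjusted over the list alone, median 0.62, adjusted p = 2.7e-14, adjusted p = 0.15 with an estimated correlation). KITLG had 2.08 ± 0.29, SPATA18 1.98 ± 0.18, TP53I3 1.92 ± 0.14, FAS 1.45 ± 0.13, GDF15 1.37 ± 0.19 and MDM2 0.79 ± 0.10. CDKN1A rose by 0.75 ± 0.14 and had 0.57, under 1.5-fold, without QUE replicates 2 and 3. Among inflammatory genes, 8 of 18 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.50, adjusted p = 0.0068, adjusted p = 0.30 with an estimated correlation). CXCL8 had 2.19 ± 0.54, IL6 1.92 ± 0.25 and TNFAIP3 1.63 ± 0.27. Of the immediate early genes, 5 of 14 rose (6 adjusted over the list alone, median 0.48, adjusted p = 0.0026, adjusted p = 0.41 with an estimated correlation). MAFF had 1.02 ± 0.19 and DUSP1 0.89 ± 0.17. Of the NRF2 targets, 8 of 26 rose (9 adjusted over the list alone, median 0.41, adjusted p = 4.8e-05, adjusted p = 0.45 with an estimated correlation). AKR1C1 had 2.00 ± 0.48 and HMOX1 1.51 ± 0.39. Without the library labelled QUE replicate 2, NQO1 had 0.22 ± 0.08 and SRXN1 0.48 ± 0.10, both under 1.5-fold. Of the unfolded protein response chaperones, 5 of 20 rose (5 adjusted over the list alone, median 0.30, adjusted p = 4.7e-06, adjusted p = 0.41 with an estimated correlation). DNAJB9 had 1.11 ± 0.16 and DNAJC3 0.69 ± 0.14. Of the ATF4 genes, 7 of 24 rose (7 adjusted over the list alone, median 0.38, adjusted p = 0.020, adjusted p = 0.74 with an estimated correlation). ATF3 had 1.52 ± 0.21 and PPP1R15A 1.33 ± 0.27. This call was lost without QUE_DMSO replicate 3 (0.27, adjusted p = 0.072), which stood apart in the NRF2 list at 8.65. Of the heat shock genes, 2 of 19 fell (2 adjusted over the list alone, median -0.24, adjusted p = 0.015, adjusted p = 0.68 with an estimated correlation). HSPA4L had -1.63 ± 0.36. Of the cholesterol genes, 5 of 17 fell (5 adjusted over the list alone, median -0.38, adjusted p = 0.038, adjusted p = 0.74 with an estimated correlation). EBP had -1.06 ± 0.16. The median was -0.17 without QUE replicate 3 (adjusted p = 0.047). Among G1/S genes, 7 of 31 fell and 1 rose (6 and 0 adjusted over the list alone, median -0.22, adjusted p = 0.018, adjusted p = 0.82 with an estimated correlation). POLA1 had -1.34 ± 0.23, and 4 members fell without QUE replicate 3. Other large rises were TREM2 (at least 1.57), SHC4 (2.42 ± 0.26), the ligand BMP2 (2.33 ± 0.27) and FEZ1 (at least 2.02). The library labelled QUE replicate 2 stood apart, with an NRF2 list mean of 8.45 and a 3' minus 5' ACTB signal of 1.52. Without it 2172 genes were called, 1053 higher and 1119 lower, 1478 of them shared with the full set, 11 ATF4 genes rose, and the calls of the G1/S list (adjusted p = 0.34) and the cholesterol list (adjusted p = 0.10) were lost. The ACTB signal was 0.38 higher in QUE than in its control (exact permutation p = 0.028, adjusted p = 0.31). That of GAPDH differed by -0.023 (exact permutation p = 0.19, adjusted p = 0.43).

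**Figure D3:**
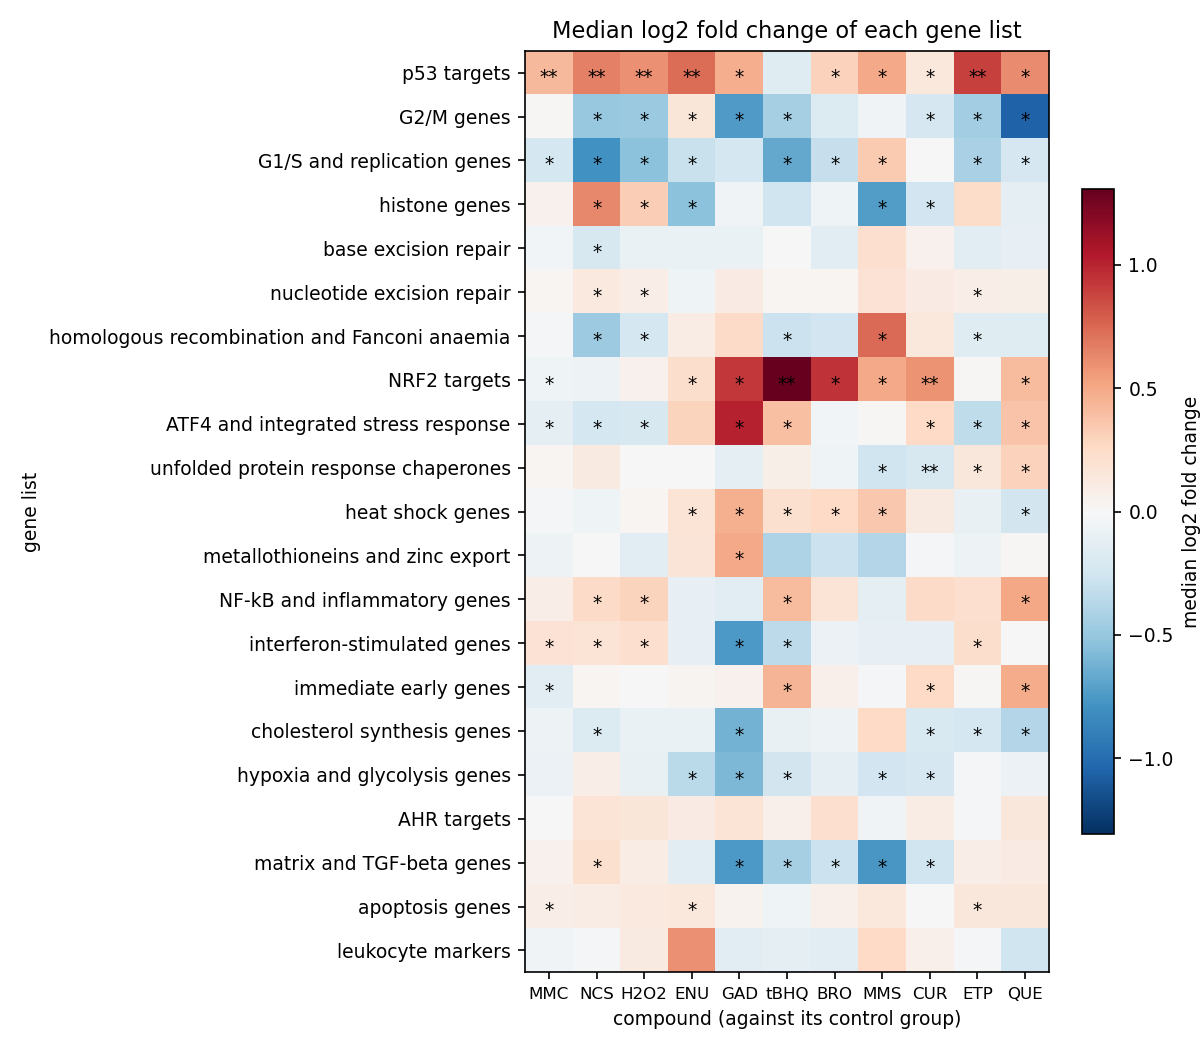
Median log2 fold change of the 21 tested gene lists (down the side) in the 11 compounds (across), coloured from lower to higher. One star marks an adjusted p under 0.05 with the preset correlation and a double star also with an estimated correlation, with NRF2 targets at 1.31 in tBHQ and p53 targets at 0.89 in ETP.

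**Figure D4:**
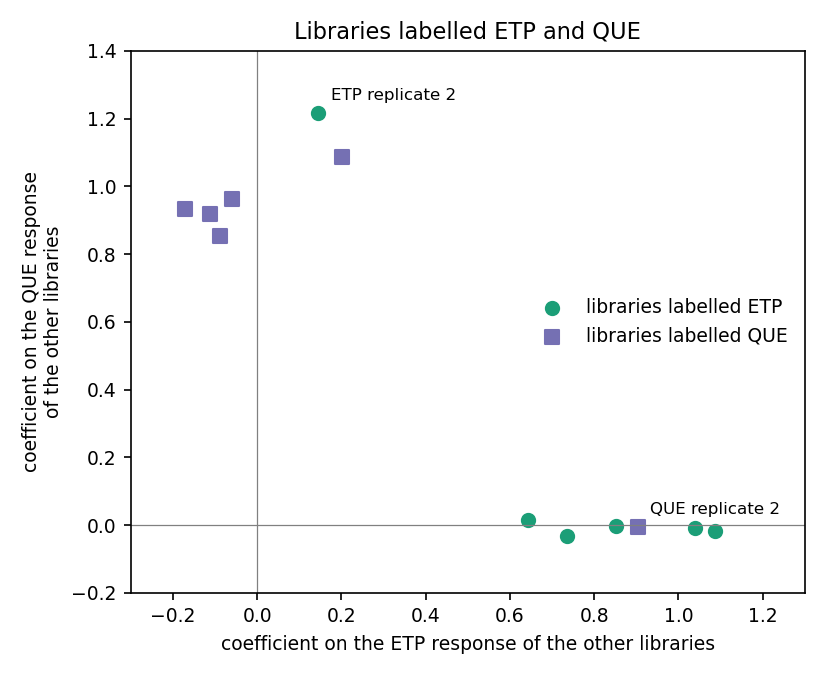
Coefficients of each ETP and QUE library on the mean ETP response (across) and the mean QUE response (up), without unit, taken from the other libraries with those numbered 2 left out. The library labelled ETP replicate 2 has 0.14 and 1.22, and the library labelled QUE replicate 2 has 0.90 and -0.01.

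Of 231 list tests, 101 passed, 52 upward and 49 downward, and 8 of these passed with an estimated correlation. The 8 were p53 targets in MMC, NCS, H2O2, ENU and ETP, NRF2 targets in tBHQ and CUR, and unfolded protein response chaperones in CUR. Where the median, mean and test of a list differed in sign, the list was not called. In means per sample the G2/M list was lower in NCS (-0.49, adjusted permutation p = 0.018), GAD (-0.75, 0.0042), tBHQ (-0.46, 0.015) and QUE (-1.17, 0.0042), and did not pass in MMC (-0.01, 0.94), H2O2, ENU, BRO (-0.20, 0.32), MMS (-0.10, 0.53), CUR and ETP. The NRF2 list was higher in ENU, GAD, tBHQ, BRO, MMS and CUR (0.0042 each) and QUE (0.0079), and did not pass in MMC (0.31), NCS (0.23), H2O2 (0.28) and ETP (0.35). These permutations ignored the replicate pairs, and no paired version was run. A list that did not pass is therefore not shown to be unchanged.

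The compounds were compared with each other in 1 fit of all groups, across separately normalized sets where their controls differed. These contrasts, and the counts and correlations across compounds below, kept the libraries labelled ETP replicate 2 and QUE replicate 2. No contrast without them is given. ETP had the widest spread between replicates, with an SD of a difference of up to 0.73, which can hide differences. Between any pair of ETP, NCS and H2O2 at most 2 genes were called, which does not show that they act alike. The p53 list was lower in H2O2 than in ETP (median difference -0.26, adjusted p = 2.3e-18, adjusted p = 0.0083 with an estimated correlation). ENU and MMS, which add ethyl and methyl groups to DNA, were given at different doses, 2 mM and 200 µM. Between them 899 genes differed, 447 higher in ENU and 452 lower. The p53 list was higher in ENU by a median of 0.26 (adjusted p = 1.0e-08, adjusted p = 0.16 with an estimated correlation), and TP53I3 by 1.15 ± 0.22 (adjusted p = 7.1e-05). Replication genes were lower in ENU, with a median difference of -0.74 (adjusted p = 2.6e-05, adjusted p = 0.71 with an estimated correlation). CDKN1A had a difference of -0.30 ± 0.15 (adjusted p = 0.18) and MDM2 of -0.26 ± 0.15 (adjusted p = 0.22). GAD and tBHQ differed in 2952 genes, and the p53 list was higher in GAD by a median of 0.38 (adjusted p = 5.3e-06, adjusted p = 0.32 with an estimated correlation). Of 55 pairs of compounds, 42 differed in the p53 list, 13 with an estimated correlation, and 46 in the NRF2 list, 20 with an estimated correlation.

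Some genes moved the same way under most compounds. In at least 6 of 11 compounds 67 genes were higher and 58 were lower, and the higher ones held 17 p53 targets and 4 NRF2 targets. With the mean of probe sets there were 76 such genes in place of 125. FADS3, a desaturase family member, was higher in 11, from 0.68 in MMS to 2.00 in ENU. GREB1, TP53INP1, GPC1 and CDKN1A were higher in 9, and AKR1B10, ACER2, SERPINB5, FAS, PPM1D, MTURN, IL12A, PLK3 and MDM2 in 8. MAP2K6, a p38 kinase activator, fell in 8 compounds, to -1.33 or lower in GAD, and MCM5 fell in 8, to -1.14 in NCS. AKR1C1, NMRAL2P and NECTIN4 were higher in 7, and LRRC17 lower in 7. The 6 compounds set against DMSO_pooled share its samples, and in simulated data with no change 0 genes were called in at least 2 of them. A simulated comparison had at most 3 calls, while another division of the MMC and control samples gave 489. The simulation may lack a structure of the real samples, so it does not show what shared controls add.

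Among pairs with separate controls, fold changes across genes correlated most between H2O2 and ETP (r = 0.756), NCS and ETP (0.735) and GAD and MMS (0.724), and least between NCS and MMS (-0.200). The median over all 55 pairs was 0.304. NCS and H2O2, which share a control, had 0.844, or 0.61 with its samples divided between them. Simulated unchanged groups against that control gave 0.45 for this pair, and a covariance of 0.0092 against 0.048 observed. Genes are not independent replicates, so these describe likeness only. The 15 pairs sharing a control had a median of 0.240, or 0.128 when the control samples were divided between both compounds, and simulated unchanged groups gave 0.43 to 0.52.

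Long genes were frequent among the falls in GAD, ENU and MMS. Of the genes called lower, 39.3% in GAD, 44.9% in ENU and 43.5% in MMS spanned over 100 kb, against 18.9% of all tested genes. The share was 30.8% in CUR, 26.2% in QUE, 24.4% in BRO, 23.9% in ETP, 23.7% in tBHQ, 21.1% in H2O2 and 11.7% in NCS. Among the genes called higher it was 31.6% in MMC, 27.5% in tBHQ, 26.1% in H2O2 and 25.3% in NCS. It was 19.0% in ETP, 18.75% in CUR, 17.9% in QUE and 15.5% in BRO. In MMS, ENU and GAD it was 12.9%, 12.4% and 7.9%. The ACTB end signal given above was higher by 0.43 in GAD (exact permutation p = 0.0022, adjusted p = 0.048). In QUE it was higher by 0.38 (exact permutation p = 0.028, adjusted p = 0.31).

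**Figure D5:**
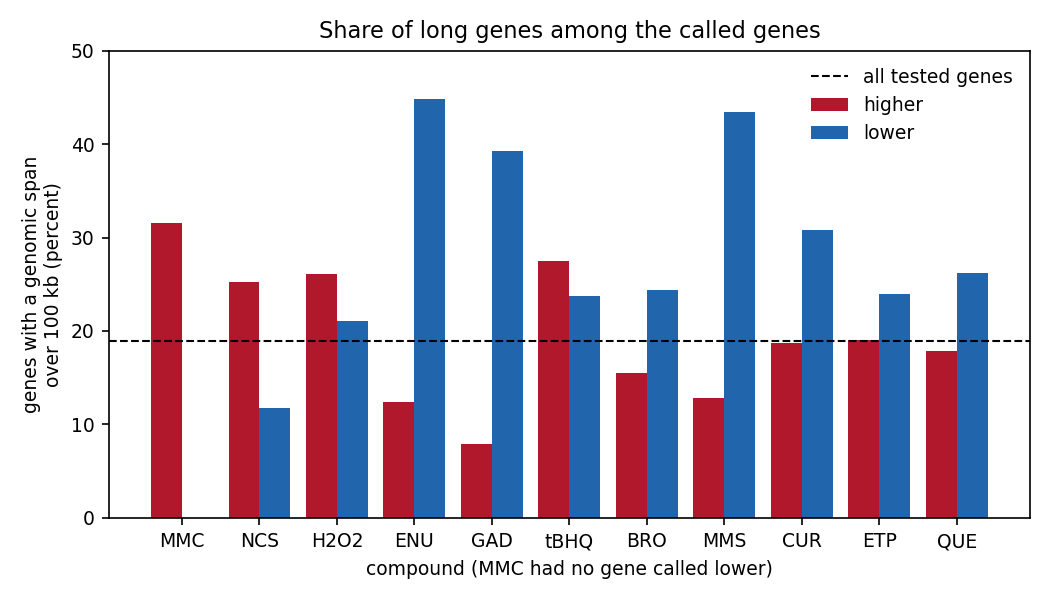
Percent of genes called higher and lower with a genomic span over 100 kb, for each compound, with the share of all tested genes (18.9%) as a dashed line. Lower genes stand at 44.9% in ENU, 43.5% in MMS and 39.3% in GAD.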

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

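The tests of exchanged labels, mixed RNA and RNA quality in the ETP and QUE libraries were chosen after the results were seen. So were those on tBHQ and those of RNA degradation in ENU and MMS. The divisions of the samples were chosen before. The other tests on long genes were recorded beforehand, but address a pattern seen among the falls in these same data. Across 6 measures in 17 groups, 13 of 102 had a sample far from the rest of its group, against 5.1 by chance. In mean log2 of the p53 list this was tBHQ replicate 1 at 8.07. In the NRF2 list they were H2O2 replicate 3 at 8.60, MMS replicate 1 at 8.75, the library labelled QUE replicate 2 at 8.45 and QUE_DMSO replicate 3 at 8.65. In the G2/M list they were the library labelled ETP replicate 2 at 7.35 and QUE replicate 3 at 6.86. In CDKN1A it was MMS_CTL replicate 3 at 8.10, and in the 3' minus 5' ACTB signal tBHQ replicate 4 at 0.75 and the library labelled QUE replicate 2 at 1.52. In the upper quartile they were H2O2 replicate 2 at 6.19, MMS replicate 4 at 5.99 and MMS_CTL replicate 3 at 5.54.

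Probe sets outside the gene comparisons, because they match no gene or several, also changed against the controls. Of 3867 tested, 3 were called in MMC, 55 in NCS, 19 in H2O2, 385 in ENU, 1025 in GAD, 319 in tBHQ, 314 in BRO, 321 in MMS, 54 in CUR, 72 in ETP and 489 in QUE.

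The libraries labelled ETP replicate 2 and QUE replicate 2 stood apart from their groups, and no biological explanation was tested. Mixed RNA would give coefficients between both responses, but the library labelled ETP replicate 2 had 1.22 on the QUE response and 0.14 on the ETP response. Exchanged labels would give each library the response of the other compound. The library labelled QUE replicate 2 had -0.0052 on the QUE response and 0.90 on the ETP response. Both libraries met this prediction. Each of the other ETP and QUE libraries had at least 0.64 on the response of its own compound and at most 0.20 on the other. No relabelled fit was run, so exchanged labels stay open. The ETP and QUE results keep both libraries as labelled, except where a library is said to be left out. RNA quality stays open for the library labelled ETP replicate 2. Its 3' minus 5' GAPDH signal of 0.216 was above the 0.213 of the next, a small margin beside the SD of 0.087 in ETP. Its ACTB signal was 3.19 against at most 2.50. These end signals do not address why that library had the QUE response. In the library labelled QUE replicate 2 the ACTB signal of 1.52 lay within 1.39 to 2.30, which argues against RNA quality there.

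Long genes were frequent among the falls in GAD, ENU and MMS. Expression level is argued against, since within 5 bins of mean expression the median Spearman rho of fold change with genomic span in GAD was -0.18, and so is any strong response on this array, with a rho of 0.013 in tBHQ and 0.011 in QUE, although 23.7% and 26.2% of their lower genes spanned over 100 kb against 18.9% of all. RNA degradation stays open in GAD, with the ACTB end signal higher by 0.43, and in MMS, with an upper 95% bound of 0.34, and is argued against in ENU, where that bound was 0.24. The GAPDH end signal differed by 0.040 in GAD (95% interval -0.009 to 0.088) and by -0.022 in MMS (-0.087 to 0.042). The ACTB difference in GAD was thus not seen in GAPDH. In QUE, with its rho of 0.011, the ACTB end signal was higher by 0.38 (exact permutation p = 0.028, adjusted p = 0.31). That difference did not pass after adjustment, so QUE does not decide whether degradation lowers long genes. A link with transcribed length stays open as well, since the weakest rho of the 3 compounds was -0.092, and without the filter on low genes rho was -0.018 in MMS, -0.047 in ENU and -0.085 in GAD. A biological effect of the compounds on long genes was not tested.

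The p53 list did not rise in tBHQ, although the design text gives a matched rise of p53 protein. Array noise hiding a rise is argued against by the upper 95% bound of 0.017 for the list mean. Untreated or mislabelled libraries are argued against by the NRF2 list, whose lowest tBHQ value exceeded the highest control by 1.34. A normalization shift is argued against by a median of at most -0.17 under both rescalings. A difference of the compound itself, such as its time course, may remain and was not tested.

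Other divisions of the samples into groups of the same sizes were counted, 100 for each comparison with the real one included. In all 11 at most 4 divisions gave as many genes, which argues against chance but was not adjusted over the comparisons. No other division did so in NCS (281 genes, highest other 146), ENU (1249, 510), GAD (3011, 1426), tBHQ (1130, 0), BRO (850, 2), MMS (1267, 174), ETP (308, 4) and QUE (1499, 0), where 1 of 100 was as large. In MMC 2 were as large (19, highest other 489), in H2O2 4 (107, 687) and in CUR 2 (253, 394). In these comparisons another division gave more genes than the real one, so this count alone does not exclude chance there. The high one in MMC set replicates 1 and 2 of compound and control with MMC replicate 3 against the rest. In H2O2 those with 687 and 565 genes set replicates 1 and 2 of both with DMSO_pooled replicate 4 or 3 against the rest, which points to a structure of the samples that follows the replicate numbers in part. The other one there (114 genes) set DMSO_pooled replicates 3 to 6 and H2O2 replicate 6 against the rest, and the one in CUR exchanged CUR replicate 5 and CUR_DMSO replicate 2. Among the 32 divisions that part every pair, only the real one was as large, with highest others of 1 in MMC, 1195 in GAD and 0 in NCS, H2O2, ENU, tBHQ, BRO and CUR. With the replicate block MMC (60 genes) and H2O2 (224) had 16 divisions each, too few for a share under 0.05, with 0 in every other one. CUR had 448 against 0 in the others of 32.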

How the results depend on the processing

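The block without the number-2 libraries of ETP and QUE, the removals of chosen libraries and of shared list members and the group means set to 4 were added after seeing the data, and the other alternatives came before. Except where a cause is given, the cause was not tested. Another control was not run, because it would cross separately normalized sets. Under the filter at 6, variances with trend and robust estimation, a shift of medians and quantile normalization, the 11 gene counts stayed within 1.5 times and the p53 list kept its direction and side of the threshold in every comparison. Of 983 results for named genes, 585 were called, 105 of these lost the call in a fit with 1 library left out and 130 under another alternative, and 1 changed direction, CHORDC1 in QUE, at 0.11 (adjusted p = 0.36) as the mean of probe sets. Signal over background limits the genes under the filter, and the number of arrays limits the rest.

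Without a fold minimum, which by construction calls more, the counts were 31 in MMC, 885 in NCS, 217 in H2O2, 3817 in ENU, 7097 in GAD, 3672 in tBHQ, 3475 in BRO, 4029 in MMS, 588 in CUR, 584 in ETP and 3843 in QUE, and 439 genes were called in at least 6 compounds. With every probe set on its own, which tests more features, they were 486 in NCS, 2598 in ENU, 6808 in GAD, 2440 in tBHQ, 1783 in BRO, 2520 in MMS, 413 in CUR, 537 in ETP and 3275 in QUE. With the mean of probe sets they were 68 in H2O2, 551 in BRO and 161 in CUR, the genes called in several compounds were 76 against 125, and the p53 list in CUR had 0.12 (adjusted p = 0.099). Without the filter the p53 list in tBHQ had -0.13 (adjusted p = 0.037). In 1 fit of all 17 groups 167 genes were called in H2O2 and 384 in CUR. List calls lost under quantile normalization were NRF2 targets in MMC (adjusted p = 0.053), interferon genes in NCS (0.066), ATF4 genes in H2O2 (0.051) and cholesterol genes in ETP (0.056), and the last also under a shift of medians (0.052). Those gained were matrix genes in MMC (0.028, and 0.032 under the shift), G2/M genes in BRO (0.034) and inflammatory genes in CUR (0.049, and 0.041 under the shift). The shift alone gave calls to ATF4 genes in ENU (0.045), recombination genes in BRO (0.041) and base excision repair in MMS (0.037). In at least 8 compounds 16 genes were called. With group means under 4 set to 4, the genes that kept a 1.5-fold change were 16 in MMC, 258 in NCS, 100 in H2O2, 1142 in ENU, 2785 in GAD, 1045 in tBHQ, 719 in BRO, 1152 in MMS, 228 in CUR, 292 in ETP and 1426 in QUE. Without members shared with another list, the calls lost were nucleotide excision repair in NCS, H2O2 and ETP, apoptosis genes in MMC (adjusted p = 0.053), ENU (0.090) and ETP (0.051) and NRF2 targets in MMC (0.087).

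With the replicate block the counts were 60 in MMC, 428 in NCS, 224 in H2O2 and 448 in CUR, and ETP had 597 with the block and without its number-2 library. List calls lost with the block were nucleotide excision repair in NCS (adjusted p = 0.11) and ATF4 genes in H2O2 (0.22). Those gained were G2/M genes in MMC (0.0025) and BRO (0.0063), cholesterol genes in MMC (0.0048) and H2O2 (0.012), matrix genes in MMC (0.00093) and H2O2 (0.015) and recombination genes in BRO (0.0063), and all of these were above 0.3 with an estimated correlation. In the 8 comparisons paired by number the block changed no other list call. In those read as unpaired the block gave 1251 genes in MMS, 369 in ETP and 1591 in QUE, where 0, 4 and 3 of 6 samples correlated best with their own number, and no list call changed in QUE. In ETP nucleotide excision repair was lost (0.057) and heat shock (0.032), histone (0.044) and inflammatory genes (0.024) were gained, and in MMS cholesterol genes were gained (0.049). With an estimated correlation the p53 list lost its call in GAD (0.48, adjusted p = 0.45), BRO (0.30, adjusted p = 0.16), MMS (0.50, adjusted p = 0.34), CUR (0.13, adjusted p = 0.74) and QUE (0.62, adjusted p = 0.15). Of 42 pairs of compounds that differed in the p53 list, 13 did so with an estimated correlation.

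With 1 library left out in turn, the gene counts ranged from 11 to 27 in MMC, 192 to 502 in NCS, 35 to 167 in H2O2, 1180 to 1388 in ENU, 2902 to 3155 in GAD, 1092 to 1243 in tBHQ, 725 to 1007 in BRO, 1199 to 1422 in MMS, 155 to 587 in CUR, 219 to 455 in ETP and 1186 to 2172 in QUE. The p53 list median ranged from 0.43 to 0.50 in MMC, 0.60 to 0.69 in NCS, 0.56 to 0.64 in H2O2, 0.69 to 0.76 in ENU, 0.42 to 0.48 in GAD, -0.20 to -0.12 in tBHQ, 0.27 to 0.35 in BRO, 0.44 to 0.53 in MMS, 0.10 to 0.16 in CUR, 0.83 to 0.90 in ETP and 0.55 to 0.67 in QUE. Without H2O2 replicate 2 the cholesterol (adjusted p = 0.029), matrix (0.045) and base excision repair lists (0.044) were gained. Without tBHQ replicate 1 its heat shock and hypoxia lists were lost (0.070 each).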

Other observations

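Markers of cell types other than fibrosarcoma cells and AHR targets were tested as lists fixed in advance. The AHR list, of xenobiotic metabolism genes, passed the test in no compound. AHRR, the repressor of that receptor, fell in GAD (-1.23 ± 0.18) and MMS (-1.13 or lower), and CYP1A1 rose in ENU (at least 0.18 over the filter level, adjusted p = 0.022), a call lost without ENU replicate 1 and without DMSO_pooled replicate 2, 3, 4 or 5. The leukocyte list had 3 tested members and passed in no compound, although LCP1, an actin bundling protein also made by many tumour lines, rose in ENU by 1.22 ± 0.13. Of the epithelial markers 1 was tested, KRT7, which fell in GAD at -1.34, in tBHQ at -1.29, in BRO at -0.59 and in QUE at -0.60. With 1 library left out in turn, its call was lost in 6 of 12 fits in BRO and 9 of 12 in QUE. No hepatocyte marker passed the filter.

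Metallothioneins, which bind zinc and copper, passed as a list in GAD alone of the 11 compounds (adjusted p = 0.033, or 0.62 with an estimated correlation), and the difference from the others was not tested. Without tBHQ replicate 1 they also passed in tBHQ, downward (-0.48, adjusted p = 0.032, or 0.60 with an estimated correlation). In tBHQ the member MT1E fell, at -0.92 ± 0.27, and 2 members fell without tBHQ replicate 1 or 4.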
